A study of Mus musculus with 5 samples.

How the data were processed

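The data were 5 tables of UMI counts per gene and cell barcode, 1 per library, from cells sorted for a Col1a1 reporter from the spinal cord of healthy mice (3 libraries) and mice with EAE (2 libraries). The authors deposited these tables as raw counts, which the values bear out as whole numbers with totals that differ between barcodes. Per the labels' protocols, cords were dissociated chemically and mechanically, single reporter-positive cells were sorted, and libraries were made with the 10x Genomics v2 protocol. Per the submitters' processing notes, Cell Ranger 2.1.1 and Seurat 3 were used with genome build mm10. Settings of cell calling, the annotation release and any filter on barcodes before deposit are not given in the sources used here. The tables of the first batch held 28692 genes and those of the second 27998, and the 27998 shared genes carried 99.5% to 100% of the UMIs. The labels of Healthy 3 and EAE 2 carry a lane, and the protocols name a pair of sequencer models without stating which library ran on which, so the batches were taken from the labels that carry a lane and those that do not. Gene positions were taken from an annotation of the same build.

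Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept. The doublet caller scrublet, run per library through scanpy 1.11.5, marked 31 of 6904 barcodes (0.449%). Under 0.5% was taken as too low to rely on, so doublets were treated as not removed, and whether the tables held few doublets was not tested. Counts were log-normalised to 10000 UMIs per cell, 2000 variable genes and 30 principal components were used with 15 neighbours, and cells were clustered with Leiden at resolution 1 (leidenalg 0.10.2). Clusters were named from 17 lists of markers fixed before the data were examined. A cluster took the name of the list with the highest mean score if at least 3 of its markers were detected and the 10 leading genes held no more markers of another class than of its own. For classes other than fibroblasts at least 1 own marker had to be among those genes, so most fibroblast-like clusters had none there. Clusters with a median UMI count under 1/3 of their library's and no own marker there were also left unnamed. The markers were fixed beforehand and this rule was not. Cluster 7 (Fmod, a tenocyte marker) and cluster 8 (Comp and Slc47a1, markers of chondrocytes and arachnoid barrier cells) had more markers of another class than of fibroblasts, and cluster 14 had no own marker there. Cells were summed per library and class, with at least 20 cells per library, because cells are not replicates.

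UMI sums were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM, its filter on low counts, a term for batch and a term for state, robust) and Benjamini-Hochberg adjustment with a threshold of 0.05. CPM of single genes are over library sizes scaled by TMM, so they differ from UMIs over plain sums. Adjusted p-values for genes are from edgeR unless DESeq2 1.42.0 is named. The standard error is the size of the log2 fold change over the square root of F. Lists of genes, 24 in all and fixed before the data were examined, were tested with camera (limma 3.58.1, preset correlation 0.01, and an estimated correlation) and fry. With 5 libraries and terms for batch and state, little is left to estimate that correlation from. Not passing with an estimated correlation therefore does not show that a list was unchanged. Shares were compared with exact two-sided permutation tests over the 10 splits of 5 libraries. The p-value was the smaller tail doubled, which cannot go under 0.2. The plan made beforehand gave a lower limit than that, which holds for 1 side or for a test on the absolute difference. Intervals of shares are exact Clopper-Pearson 95% intervals, and limits for a count of 0 take 3 counts. Both cover counting error only. The share of cycling cells used at least 2 UMIs of 6 genes after thinning to 1000 UMIs.

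Genes were named by a rule fixed before the data were examined. In fibroblast-like cells these were the 12 largest rises and 12 largest falls past the threshold with a mean of at least 20 CPM, no overlap between the states and, for rises, a level of at least 20% of that in the highest other class. From each list up to 2 risers and 2 fallers past the threshold were named, and Col1a1 in any case. In other classes up to 5 rises and up to 5 falls were named under the same conditions, no overlap between the states included. Of rises that met the first conditions, 138 in all, 2 fell under the limit set for RNA of other classes (Gja4 and Id2), and 386 falls met them. Tnc and Cxcl9 were added after their values were seen, and H2-Eb1 as the other measured gene of the class II list.

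Alternatives fixed beforehand were DESeq2, other scalings, no filter on low counts, no batch term (for fibroblast-like and all sorted cells), each library left out, other filters and classes of cells, equal cells per library, thinning, and leaving out immune and neural markers. The batch term was kept when a library was left out. Fits without Healthy 3 or without EAE 2 thus both took the fold from the first batch alone. Fits without EAE 1 took it from the second batch alone, so these are not separate checks on all libraries. Counting each barcode once, alone and with the others, leaving out both first-batch Healthy libraries, adding clusters 7 and 8, removing the 5% highest doublet scores, testing cluster 5 alone and dropping the batch term in other classes were added after seeing the data. On simulated counts with 100 genes changed by 1 on the log2 scale and 100 by 2, the test recovered 42 and 98 for fibroblast-like cells with 26 false calls among 9208 unchanged genes. It recovered 49 and 92 counted once, 27 and 89 for cluster 7, 21 and 75 for mural-like cells, 12 and 68 for cluster 5 and 52 and 92 for all cells. False calls in these were 9 counted once, 14 for cluster 7, 1 for mural-like cells, 6 for cluster 5 and 14 for all cells. Except in mural-like cells, false calls were a larger share of all calls than the threshold on the adjusted p-value aims for. The reported calls may thus hold more false ones than that threshold implies. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3 were used. The median UMI count per barcode ran from 615 to 5002.5, so that low genes are measured less precisely in Healthy 1 and Healthy 2.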

Results

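Single-cell RNA-seq was carried out on cells sorted for a green fluorescent reporter of the Col1a1 gene from the spinal cord of mice on a C57/BL6 background. Col1a1 encodes a chain of type I collagen and is a usual mark of fibroblasts. The libraries fell into 3 from healthy mice (Healthy 1, Healthy 2 and Healthy 3) and 2 from mice with experimental autoimmune encephalomyelitis (EAE 1 and EAE 2), a model in which an immune response against myelin inflames the cord. The title of EAE 1 carries no number, and its number here follows the order of the samples. Healthy 1, Healthy 2 and EAE 1 were taken as the first batch, and Healthy 3 and EAE 2, whose labels carry a sequencing lane, as the second. The tables held 2293, 1118 and 376 barcodes for Healthy 1 to 3 and 2156 and 1262 for EAE 1 and EAE 2. Their UMI totals were 1990869, 1949879 and 1588693 in the Healthy libraries and 10775024 and 7317084 in the EAE libraries. The median UMI count per barcode was 615, 913 and 4258 in Healthy 1 to 3, and 4230.5 and 5002.5 in EAE 1 and EAE 2. No label says that the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical.

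Many barcodes of the first batch occurred in more than 1 library. Healthy 1 and EAE 1 shared 1239 barcodes where chance gave 6.71, and the UMI count of such a barcode in Healthy 1 was a median of 0.0939 times that in EAE 1. Healthy 2 and EAE 1 shared 683 barcodes against 3.27 by chance, with a median ratio of 0.104, and Healthy 1 and Healthy 2 shared 996 against 3.48. Between the 2 libraries of the second batch 1 barcode was shared, where chance gave 0.64. A barcode that had more UMIs in another library of its batch is called a copy here. Copies made up 1549 barcodes of Healthy 1 (67.6%, with 46.1% of its UMIs), 684 of Healthy 2 (61.2%, with 27.9%) and 2 of EAE 1. Of the barcodes of Healthy 2, 89.1% were also in Healthy 1. As deposited, the libraries of the first batch are thus not independent samples, and p-values as deposited partly rest on the likeness of shared barcodes. Values are given with all barcodes as deposited, the design fixed before the data were examined. Beside many of them, but not all, stand values with each barcode counted once in the library where it had most UMIs, which was chosen after seeing the data. A value without such a mark is as deposited.

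**Figure D1:**
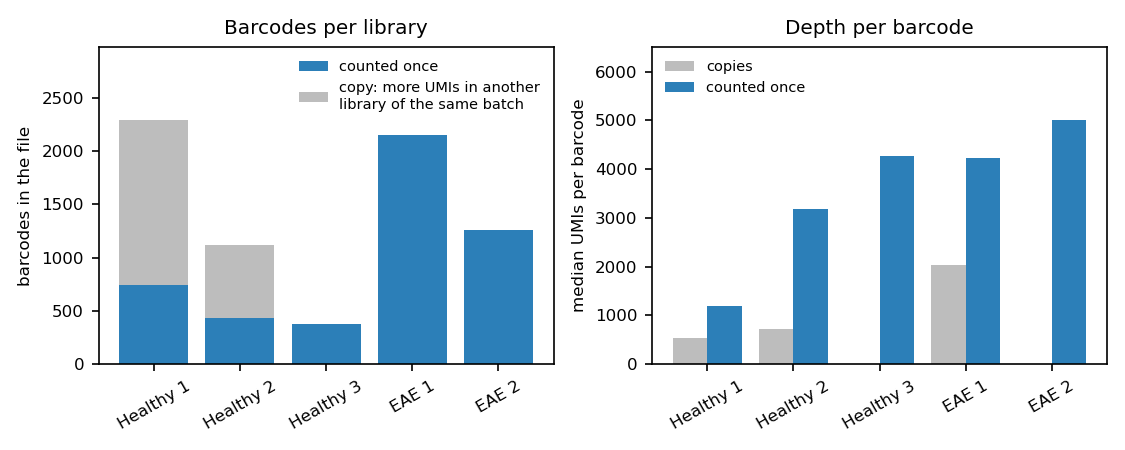
Bars give, per library, the number of barcodes split into copies and barcodes counted once (left) and the median UMIs per barcode of each kind (right). Copies had a median of 535 UMIs in Healthy 1 and 721 in Healthy 2, against 1193 and 3178 for the barcodes counted once, and EAE 1 had 2 copies.

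After filtering, 6873 of 7205 barcodes were kept, of which 4651 remained when counted once. Clustering gave 17 groups. Clusters 0, 1, 2, 4, 5, 6, 9, 12, 13 and 16 were fibroblast-like by the markers fixed beforehand, cluster 3 was arachnoid-barrier-like (led by Ptgds and Igfbp3), clusters 11 and 15 were mural-like (vessel wall cells, led by Myh11 and Acta2 or by Rgs5 and Kcnj8), and cluster 10 (158 cells, led by Fcer1g and H2-Ab1) took the name of myeloid cells. It is called immune-like here, because other clusterings also gave a lymphocyte cluster, which this one did not. With barcodes counted once before clustering, a cluster led by Cd3g, Cd3d and Nkg7 held 33 and 21 cells of EAE 1 and EAE 2, and 1 led by H2-Aa and H2-Ab1 held 90 and 8. With at least 1000 UMIs such clusters held 32 and 20 and 83 and 7 cells, and with no cell filter 35 and 22 and 89 and 7. Cluster 7 (742 cells, led by Clec3b, Fmod and Igfbp2), cluster 8 (57 cells, led by Comp) and cluster 14 (149 cells, led by the pigment genes Dct, Pmel and Mlana) stayed unnamed. Counted once, the Healthy fibroblast-like cells lay mainly in cluster 5 (347, 227 and 171 of 391, 280 and 215 cells). Those of EAE lay mainly in clusters 4 (366 and 296 cells), 13 (261 and 407), 2 (384 and 51) and 6 (259 and 145). Clusters 0, 1 and 9 were made mostly of copies.

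The first comparison asked how the make-up of the sorted cells differed between EAE and healthy cords. Immune-like cells (cluster 10, lymphocytes included) were 6.48% of EAE 1 and 2.38% of EAE 2, against 0.177%, 0.0903% and 0% of Healthy 1 to 3 (0 of 372 cells in Healthy 3, which allows a share of up to 0.806%). Arachnoid-barrier-like cells were 10.1% and 3.28% of the EAE libraries and 0.708%, 0.812% and 1.61% of the Healthy ones. Counted once the latter were 0%, 0.235% and 1.61%, and 0 of 723 cells allows a share of up to 0.415%. Of the clusterings run, this one alone gave this class: at resolution 0.5, with no cell filter, with predicted doublets kept, without the 5% highest doublet scores, with at least 1000 UMIs and counted once before clustering, no cluster took its name. Igfbp3 was then among the 10 leading genes of a fibroblast-like cluster, or with at least 1000 UMIs of an unnamed one. Cluster 7 held 5.46% ± 0.99 of EAE cells (SD, n = 2) and 19.5% ± 13.5 of Healthy cells (SD, n = 3), or 30.5% ± 11.2 of Healthy cells counted once. Mural-like cells were 3.14% ± 0.73 in EAE and 4.43% ± 0.83 in Healthy (6.499% ± 1.70 counted once). The exact two-sided permutation p was 0.2 for each of these 4 classes, the smallest that the test as run can give, so no share could pass 0.05. Fibroblast-like cells were 77.9% ± 9.0 of EAE and 72.0% ± 12.6 of Healthy cells (exact permutation p = 0.8). Their difference was -7.54 points in the first batch and 26.4 in the second, and 11.6 and 26.4 points counted once. It was -1.21 points without Healthy 3, -0.434 without EAE 2, 12.2 without EAE 1 and 10.8 without Healthy 2. The immune-like difference was 4.34 points, and 2.29 without EAE 1. The mural-like one was -1.29 points, -0.811 without Healthy 3 and -0.770 without EAE 2. Of EAE 1 barcodes with over 5500 UMIs, 0 of 16 immune-like ones and 506 of 507 fibroblast-like ones recurred in Healthy 1. Cluster 8 held 0.299% ± 0.27 of EAE and 1.17% ± 0.95 of Healthy cells. The within-batch differences had 1 sign in both batches for immune-like cells (6.35 and 2.38 points), arachnoid-barrier-like cells (9.38 and 1.67), cluster 7 (-7.22 and -28.3) and mural-like cells (-0.296 and -2.75). The sort for the reporter sets which cells enter these shares.

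**Figure D2:**
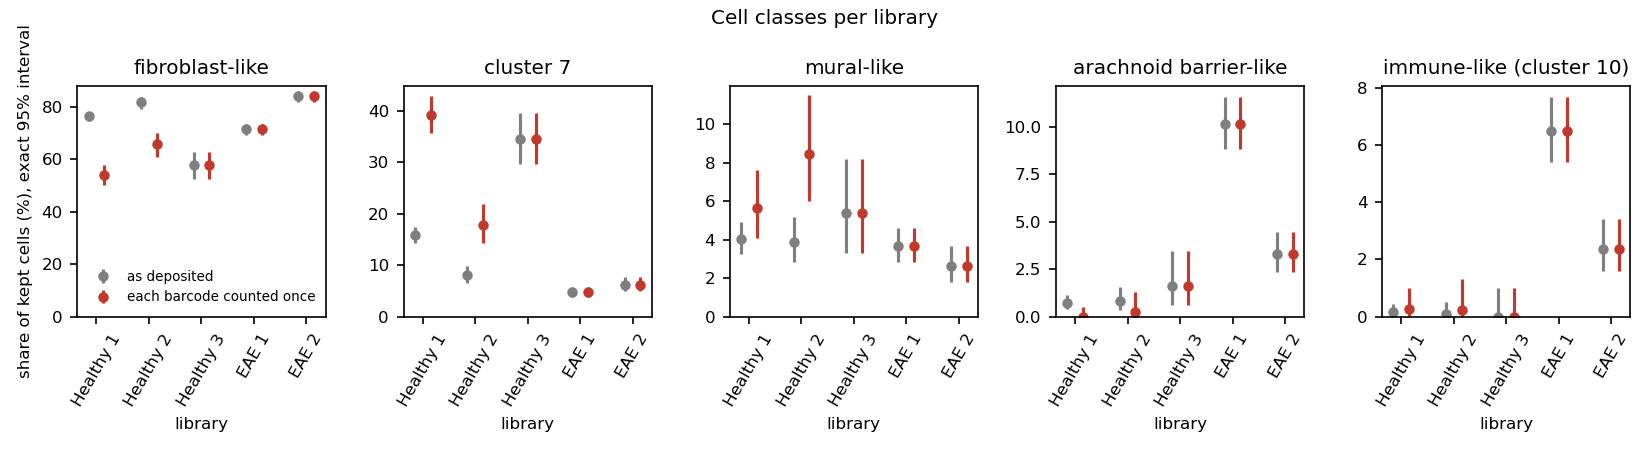
Points give the share of kept cells in percent per library for 5 classes, with exact 95% binomial intervals, as deposited (grey) and with each barcode counted once (red). Immune-like cells (cluster 10, lymphocytes included) were 6.48% and 2.38% of the EAE libraries as deposited, and at most 0.277% of any Healthy library in either count.

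The main comparison asked which genes differed between EAE and Healthy in fibroblast-like cells. Ccl19, a chemokine that attracts T cells and dendritic cells through Ccr7, had a log2 fold change of 2.56 (SE 0.19, edgeR adjusted p = 3.0e-04), with 271 and 101 CPM in the EAE libraries against 53.3, 47.9 and 13.5 in the Healthy ones. Counted once its log2 fold change was 3.42 (SE 0.33). Sik1, a kinase of the salt-inducible family, rose by 2.39 (SE 0.33) on the log2 scale. Further rises included Tnfrsf21, a death receptor (1.71, SE 0.34, adjusted p = 0.0216), Tbx3, a T-box transcription factor (1.71, SE 0.28), Eng, a co-receptor for TGF-beta (1.54, SE 0.29), Sdc4, a cell surface proteoglycan (1.47, SE 0.28), Stra6, a receptor for retinol-binding protein (1.46, SE 0.30), and Lama1, a laminin chain (1.43, SE 0.33). Fam105a (1.78), Dram1 (1.66), Chst2 (1.65) and Tns3 (1.49) completed the 12 largest rises. Counted once, the log2 fold change was 2.90 for Sik1, 3.22 for Tnfrsf21, 2.41 for Tbx3, 2.88 for Eng, 2.08 for Sdc4 and 2.26 for Stra6. It was 2.92 for Lama1, 3.51 for Fam105a, 3.72 for Dram1, 2.98 for Chst2 and 2.54 for Tns3. In each of these genes both EAE libraries lay above all 3 Healthy libraries, as the naming rule required. Without Healthy 2, Ccl19 and Sik1 passed but the other 10 did not, with log2 fold changes from 1.38 for Lama1 to 1.81 for Dram1. Markers of endothelial cells, which also express Eng, summed to 588 and 351 CPM in the fibroblast-like cells of EAE 1 and EAE 2 and to 407, 309 and 87.7 CPM in those of Healthy 1 to 3, or 103, 127 and 87.7 CPM counted once. Neutrophil markers summed to 36.9 and 23.2 CPM and to 17.7, 17.5 and 11.6 CPM.

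Dlk1, a Notch-related membrane protein that restrains fat cell formation, fell by 5.94 (SE 0.29, edgeR adjusted p = 4.1e-05) on the log2 scale, from 55.5, 72.3 and 212 CPM in the Healthy libraries to 1.33 and 2.79 in the EAE libraries. Myoc, which encodes the secreted protein myocilin, fell by 4.46 (SE 0.23), Gfra1, a receptor for glial cell line-derived neurotrophic factor, fell by 4.08 (SE 0.26), and Reln, the matrix protein reelin, fell by 3.78 (SE 0.45). Gsn, the actin-severing protein gelsolin, fell by 3.70 (SE 0.27) and Cd34, a sialomucin of progenitors and adventitial fibroblasts, fell by 3.53 (SE 0.29). Efhd1 (-4.15), Mmd2 (-4.12), Col9a2 (-4.06), Gria1 (-3.82), Abca8b (-3.48) and Idi1 (-3.47) made up the rest of the 12 largest falls. Counted once the log2 fold change was -6.31 for Dlk1, -5.00 for Myoc and -4.14 for Gsn. Both EAE libraries lay below all 3 Healthy libraries for each, as the naming rule required. Gsn, Gfra1 and Col9a2 are among the 10 leading genes of cluster 5. Counted once, that cluster held 347, 227 and 171 Healthy and 54 and 61 EAE cells. Within it Gsn fell by 1.11, Col9a2 by 1.47 and Dlk1 by 3.24. A shift in the mix of clusters and a change within cells were not told apart. Idi1 did not pass without Healthy 2 (-3.59). Col1a1, the gene of the reporter, had 7472 and 7641 CPM in EAE against 3676, 5252 and 2925, a log2 fold change of 1.02 (SE 0.21, adjusted p = 0.0321). It did not pass with barcodes counted once (1.22, SE 0.42, adjusted p = 0.106, with 2.3e-10 to 0.117 over its alternatives), nor without Healthy 1 (0.95). Markers of osteoblasts, bone cells rich in Col1a1, summed to 568, 3738 and 2.11 CPM in the fibroblast-like cells of Healthy 1 to 3 and to 229 and 29.98 CPM in EAE 1 and EAE 2. Erythroid markers summed to 20.6, 44.1 and 9.51 CPM and to 440 and 1.77 CPM. Markers of chondrocytes, which also express Col9a2, summed to 18.4, 32.9 and 43.3 CPM and to 3.20 and 4.84 CPM, and those of oligodendrocytes to 43.5, 40.6 and 57.1 CPM and to 23.2 and 23.5 CPM.

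**Figure D3:**
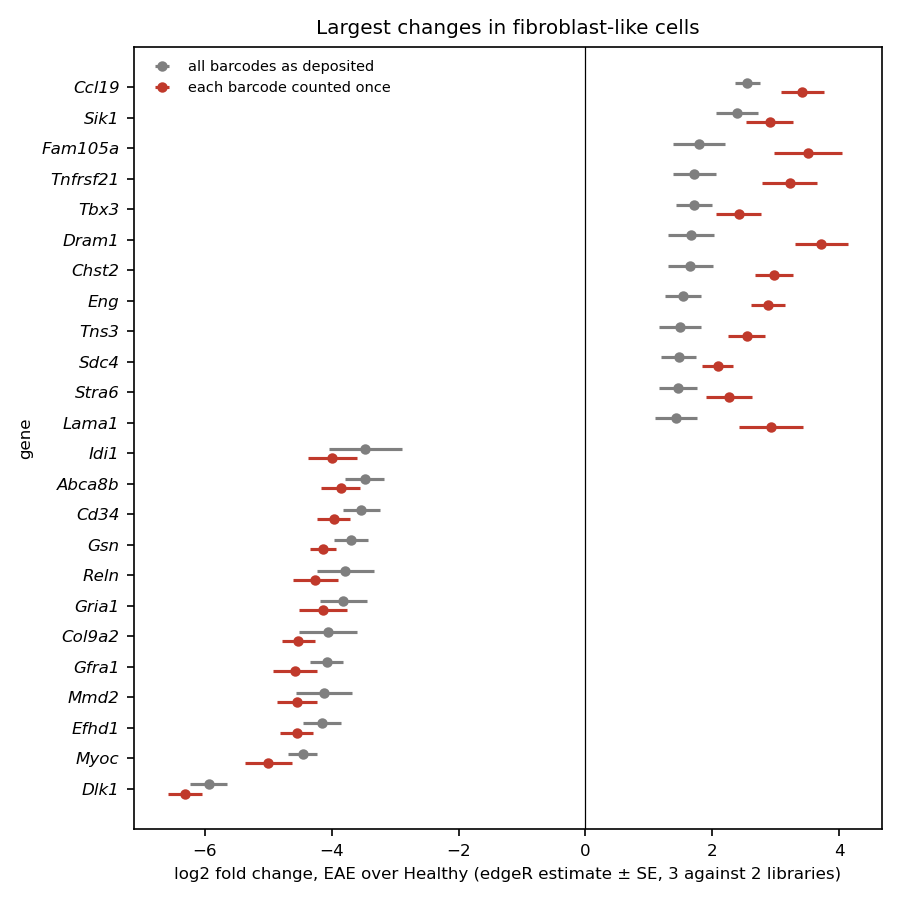
Log2 fold change of EAE against Healthy in fibroblast-like cells for the 12 largest rises and 12 largest falls, with standard errors as bars, as deposited (grey) and with each barcode counted once (red). As deposited Dlk1 stands lowest at -5.94 and Ccl19 highest at 2.56.

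In mm10, Col1a1 lies on chromosome 11 at 94936224 to 94953042 on the plus strand, Ccl19 on chromosome 4 at 42754525 to 42756577 on the minus strand, Dlk1 on chromosome 12 at 109452823 to 109463336 on the plus strand, and Myoc on chromosome 1 at 162639155 to 162649693 on the plus strand. All 4 are annotated as protein-coding, and the counts are over whole genes.

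Of 9701 genes tested in fibroblast-like cells, 232 were higher and 526 lower in EAE at an edgeR adjusted p under 0.05, and 2604 had an unadjusted p under 0.05. Counted once, 1202 of 8706 genes were higher and 1140 lower. Of the as-deposited calls tested in both, 214 of 220 rises and 521 of 522 falls were called again in the same direction, and 0 in the opposite one. Without regard to any test, both EAE libraries lay above all Healthy libraries for 1987 genes and below for 2016, where chance gives 10% on each side. Leaving out a library moved the counts of higher and lower genes to 9 and 132 without Healthy 2, 386 and 506 without Healthy 3, 1421 and 1209 without EAE 1, and 573 and 715 without EAE 2, while they were 337 and 600 without Healthy 1. Of the 75 genes named in this class, 54 kept their direction without Healthy 2 but did not pass, and the same held for 62 with no batch term. Counted once, 1330 genes were higher and 1068 lower without Healthy 2, and 931 and 828 without Healthy 3. The drop in calls without Healthy 2 was thus seen as deposited and not counted once. With the batch term, folds without Healthy 3 or EAE 2 came from the first batch alone, and those without EAE 1 from the second. With barcodes counted once, the counts were 1948 and 1547 without Healthy 1, 523 and 450 without EAE 1, and 653 and 573 without EAE 2. With no batch term 1 gene was higher and 76 lower, or 977 and 933 counted once. Scaling by library totals gave 290 higher and 368 lower, with a median log2 fold change over all genes of 0.147. With barcodes counted once it gave 1687 and 880, with a median of 0.170. Over 1221 genes with a log2 fold change above 1 in the second batch, picked without use of the first batch after the data had been seen, the median in the first batch was 0.56 as deposited and 1.31 counted once, and in the second 1.66 and 1.65.

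Among matrix genes, 4 of 7 measured fibrillar collagens rose, 0 fell and 3 did not pass (5 rises and 1 fall adjusted over the list alone). The examples with the largest changes were Col5a1 (1.41, SE 0.28) and Col5a2 (1.17, SE 0.24), chains of a collagen that starts fibril assembly, and counted once these were 2.16 and 1.81. The camera test gave adjusted p = 0.0162 with a median log2 fold change of 0.98, and adjusted p = 0.447 with an estimated correlation. Fibrillar collagens did not pass without Healthy 1 (median 0.85, adjusted p = 0.107) or without EAE 2 (0.56, 0.0577), with 7.2e-04 to 0.447 over the alternatives, and the median was 0.55 without Healthy 3. Of 30 matrix glycoproteins and proteoglycans, 4 rose, 5 fell and 21 did not pass (8 and 5 adjusted over the list alone). Thbs2, a matricellular thrombospondin, rose by 1.38 (SE 0.25) on the log2 scale and Col6a3 by 1.03 (SE 0.25), while Efemp1, a fibulin, fell by 1.93 (SE 0.26) and the small proteoglycan Dcn fell by 1.85 (SE 0.19). The list's median was 0.80 with camera adjusted p = 0.0285, and adjusted p = 0.447 with an estimated correlation. Without Healthy 1 it did not pass (median 0.88, adjusted p = 0.0594, with 1.6e-08 to 0.447 over the alternatives). Counted once Col6a3 had 1.70, and 18 of the list's 30 members rose and 6 fell, with a median of 1.49. The median was 0.45 with marker scores and 0.36 with clusters 7 and 8, where the list did not pass. Col5a1, Col5a2, Thbs2 and Col6a3 did not pass without Healthy 2 (1.47, 1.26, 1.43 and 1.08 on the log2 scale), nor Col6a3 without Healthy 3 (0.57). Tenascin C (Tnc), named after its values were seen, had 128 and 107 CPM in EAE against 55.5, 50.1 and 2.26 as deposited (adjusted p = 0.224, log2 fold change 2.099, EAE above Healthy in all 5 libraries), and its Healthy values counted once were 3.74, 0 and 2.21 CPM.

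Of 21 measured matrix proteases and inhibitors, 4 rose, 1 fell and 16 did not pass (9 and 1 adjusted over the list alone). Mmp11 rose by 1.26 (SE 0.30) on the log2 scale and Ctsb, a lysosomal cysteine protease, fell by 1.33 (SE 0.23). The gelatinase Mmp9 also rose, from 4.50, 2.21 and 1.13 CPM in the Healthy libraries (6, 3 and 1 UMIs) to 11.7 and 14.9 CPM in the EAE libraries (88 and 96 UMIs). The median was 0.80 with camera adjusted p = 0.00161, and adjusted p = 0.447 with an estimated correlation. It was 1.36 without EAE 1, 0.48 without EAE 2, 0.47 with clusters 7 and 8 and 1.27 counted once, and the list did not pass with marker scores (0.25). In the list of collagen crosslinking and secretion 1 of 17 members rose, 0 fell and 16 did not pass (4 and 1 adjusted over the list alone), the riser being the lysyl oxidase Loxl2 (1.31, SE 0.21), with a median of 0.42, camera adjusted p = 0.0111 and adjusted p = 0.447 with an estimated correlation. Among 16 basement membrane genes 3 rose, 2 fell and 11 did not pass (6 and 2 adjusted over the list alone). Lama1 and Agrn, a heparan sulfate proteoglycan (1.34, SE 0.31), rose. Lama2 fell by 1.25 (SE 0.20) and Col15a1 by 0.95 (SE 0.19), and Col15a1 overlapped between the states. That list did not pass (median 0.61, camera adjusted p = 0.0614), but it did counted once (median 0.77, adjusted p = 0.00742, with 0.00671 to 0.447 over its alternatives). Basement membrane genes also passed without Healthy 3 (adjusted p = 0.0247, median 0.34), and had medians of 0.79 without EAE 1 and 0.36 without EAE 2. In these fits the folds came from 1 batch alone. Of the single genes named, Mmp11, Ctsb, Mmp9, Loxl2, Agrn, Lama1, Lama2 and Col15a1 did not pass without Healthy 2 (1.34 for Mmp11, -1.29 for Ctsb, 1.39 for Loxl2, -1.13 for Lama2). Counted once, Loxl2 had 2.03, Agrn 2.34 and Col15a1 -1.22, the last then without overlap, and Mmp9 had 0, 0 and 1 UMIs in Healthy. Crosslinking genes did not pass without Healthy 1 (median 0.38, adjusted p = 0.107, with 1.2e-05 to 0.447 over the alternatives), and their median counted once was 0.50.

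Of 10 measured contractile genes of smooth muscle and myofibroblasts 0 rose, 1 fell and 9 did not pass (3 and 1 adjusted over the list alone). The member that fell was Myl9, a myosin light chain (-1.06, SE 0.18), while the list's median was 1.32 with camera adjusted p = 0.0125, and adjusted p = 0.480 with an estimated correlation. That median was 0.57 without Healthy 3, 0.58 without EAE 2 and 2.29 without EAE 1. Counted once 8 rose and 1 fell, with a median of 2.03. The sum of mural markers in fibroblast-like cells was 917 and 1179 CPM in EAE and 701, 627 and 463 CPM in Healthy. Myl9 in EAE fibroblast-like cells was at 3.03% of its level in mural-like cells. Among 20 TGF-beta response genes 1 rose, 2 fell and 17 did not pass (7 and 4 adjusted over the list alone), with a median of 0.75, camera adjusted p = 0.0185 and adjusted p = 0.520 with an estimated correlation. Their median was 1.14 without EAE 1 and 1.02 counted once, and the list did not pass with marker scores (0.55), thinning (0.55) or clusters 7 and 8 (0.34). Cdkn1a, a cell cycle inhibitor, fell by 1.43 (SE 0.20) and Id1 fell by 1.07 (SE 0.23). Ltbp2, which binds matrix microfibrils, rose by 1.65 (SE 0.38), from 32.3, 22.9 and 1.13 CPM in Healthy to 68.5 and 23.5 CPM in EAE, with overlap between the states. Counted once there was no overlap, with 0, 0 and 1 UMIs of Ltbp2 in Healthy against 514 and 152 in EAE. As deposited, Healthy 2 decided the calls of Myl9, Cdkn1a, Id1 and Ltbp2, which had -1.005, -1.34, -0.92 and 1.68 without it.

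Of 22 interferon-gamma genes 3 rose, 0 fell and 19 did not pass (14 and 0 adjusted over the list alone), with a median of 0.97, camera adjusted p = 3.9e-06 and adjusted p = 0.447 with an estimated correlation. Psmb9, a subunit of the immunoproteasome, rose by 0.76 (SE 0.19) with overlap between the states, and Tgtp2, a GTPase, rose from 5.25, 2.95 and 0 CPM in Healthy (7, 4 and 0 UMIs) to 17.7 and 14.1 CPM in EAE (133 and 91 UMIs), at 12.2% of the level in mural-like cells. The median was 1.70 without EAE 1 and 0.65 with no batch term. Counted once 15 of 21 rose and 0 fell, with a median of 1.97. Cxcl9, a chemokine induced by interferon-gamma and named after its values were seen, had 381 and 168 CPM in EAE against 221, 212 and 1.13 in Healthy as deposited, and against 5.61, 3.52 and 1.11 counted once. Of 25 type I interferon genes 2 rose, 0 fell and 23 did not pass (2 and 0 adjusted over the list alone), with a median of 0.46, camera adjusted p = 0.00315 and adjusted p = 0.447 with an estimated correlation. Their median was 0.76 without Healthy 1 and 0.96 counted once, and they did not pass with no batch term (0.25). The risers were Ly6e (0.93, SE 0.20) and Xaf1 (0.88, SE 0.23), both with overlap between the states. Of 17 class I presentation genes 6 rose, 0 fell and 11 did not pass (10 and 0 adjusted over the list alone), among them H2-Q4 (1.17, SE 0.21) and B2m, the class I light chain (1.09, SE 0.20, with overlap between the states), with a median of 0.63, camera adjusted p = 4.1e-04 and adjusted p = 0.447 with an estimated correlation. These did not pass with no batch term either (0.48), and their median was 0.97 counted once. Of the class II list 2 members were measured, too few for a list test: Cd74, the invariant chain, rose (2.09, SE 0.42) at 0.457% of its level in immune-like cells, and H2-Eb1 had a log2 fold change of 0.24 (adjusted p = 0.764). None of the 7 risers named by rule passed without Healthy 2 (from 0.77 for Psmb9 to 2.13 for Cd74, Tgtp2 aside), and calls were also lost for Psmb9 without Healthy 1 (0.80), Ly6e without Healthy 3 (0.63) and H2-Q4 without EAE 1 (0.70). Counted once, Psmb9 had 1.47, Ly6e 1.42 and B2m 1.81, all without overlap, and Tgtp2 had 1, 0 and 0 and Cd74 1, 3 and 0 UMIs in Healthy. Myeloid markers in fibroblast-like cells summed to 36.4 and 46.3 CPM in EAE and 25.8, 20.3 and 24.3 CPM in Healthy.

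Chemokine genes moved both ways. Of 23 chemokines and cytokines 2 rose, 3 fell and 18 did not pass (4 and 3 adjusted over the list alone), with a median of 0.83, camera adjusted p = 0.0162 and adjusted p = 0.447 with an estimated correlation. That median was 0.26 without Healthy 3, 0.28 without EAE 2 and 2.74 without EAE 1. The list did not pass with no batch term (0.60), marker scores (0.52), equal cells (0.81), thinning (0.49) or clusters 7 and 8 (0.49). Csf1, a growth factor of macrophages, rose by 0.90 (SE 0.23) on the log2 scale, while the eosinophil chemokine Ccl11 fell by 2.16 (SE 0.19) and the alarmin Il33 fell by 1.40 (SE 0.25). Counted once Csf1 had 1.51, and the median of the chemokine and cytokine list was 1.01. Of 23 NF-kappaB and acute phase genes 1 rose, 1 fell and 21 did not pass (2 and 1 adjusted over the list alone), namely Nfkb2 (1.04, SE 0.26) and the metalloreductase Steap4 (-1.61, SE 0.20). The median was 0.68, with camera adjusted p = 0.0473 and adjusted p = 0.532 with an estimated correlation, and without Healthy 2 it did not pass (adjusted p = 0.0653, with 4.2e-09 to 0.532 over its alternatives). Of 9 complement genes 1 rose, 0 fell and 8 did not pass (1 and 0 adjusted over the list alone), with a median of 1.13, camera adjusted p = 0.0163 and adjusted p = 0.447 with an estimated correlation. The riser was C1ra, a protease of the C1 complex (1.13, SE 0.17). Counted once the median was 0.85 for the NF-kappaB and acute phase genes and 1.10 for the complement genes. Csf1, Il33, Nfkb2 and C1ra did not pass without Healthy 2 (0.81, -1.44, 1.14 and 1.08), Csf1 and Nfkb2 also not without Healthy 3 (0.72 and 0.77), and Nfkb2 not without Healthy 1 (1.11).

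Of 16 measured genes of cholesterol synthesis 9 fell, 0 rose and 7 did not pass (15 and 0 adjusted over the list alone), and counted once 14 of 15 fell. Idi1, which makes dimethylallyl diphosphate, fell by 3.47 (SE 0.57) on the log2 scale and the sterol oxidase Msmo1 fell by 2.32 (SE 0.31). The median was -1.72 as deposited and -2.20 counted once, with camera adjusted p = 5.8e-16 and adjusted p = 0.447 with an estimated correlation. Of 20 genes of the unfolded protein response 5 fell, 0 rose and 15 did not pass (7 and 0 adjusted over the list alone), among them the chaperone Hspa5 (-0.99, SE 0.15) and the transcription factor Ddit3 (-1.13, SE 0.23). Their median was -0.36, with camera adjusted p = 0.0185 and adjusted p = 0.447 with an estimated correlation. This list did not pass without EAE 1 (median -0.44, adjusted p = 0.137) or without Healthy 1 (-0.38, 0.0504), with 0.00374 to 0.447 over its alternatives. Idi1, Hspa5 and Ddit3 did not pass without Healthy 2 (-3.59, -0.98 and -1.03).

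Of 28 measured cell cycle genes 1 rose, 0 fell and 27 did not pass (1 and 0 adjusted over the list alone), with a median of 0.77, camera adjusted p = 3.2e-05 and adjusted p = 0.447 with an estimated correlation. The median was 2.00 without EAE 1, 0.48 with no batch term and 1.46 counted once. It changed sign to -0.09 when cells were thinned to 1000 UMIs, and the list did not pass then or with marker scores (0.39). The riser was Hist1h2ap, a histone gene, with 1.501, 1.47 and 2.26 CPM in Healthy (2, 2 and 2 UMIs) and 20.1 and 7.90 CPM in EAE (151 and 51 UMIs). It did not pass without Healthy 2 or without EAE 1. Counted once 10 of 15 members rose and 0 fell. After each cell was thinned to 1000 UMIs, 1.39% of EAE 1 and 1.12% of EAE 2 fibroblast-like cells had at least 2 UMIs of 6 cell cycle genes, against 3.44%, 3.45% and 0% of Healthy 1 to 3 (exact permutation p = 0.6). With barcodes counted once this was 0 of 231, 262 and 209 Healthy cells, which allows shares of up to 1.299%, 1.15% and 1.44%, so that the difference changed sign from -1.04 to 1.25 points (exact permutation p = 0.2). As deposited it was -2.06 points in the first batch and 1.12 in the second, -0.471 without Healthy 1, -0.465 without Healthy 2 and -2.19 without Healthy 3. The shares without thinning were 6.93% and 4.68% in EAE and 1.504%, 2.32% and 0% in Healthy. In mural-like cells, taken as a class for background, 1 of 25, 0 of 35 and 0 of 19 Healthy cells and 1 of 70 and 3 of 30 EAE cells had them. Thinning left out 1438, 558 and 6 Healthy cells and 0 and 44 EAE cells as too shallow.

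Of 20 genes of retinoid handling and leptomeninges 4 rose, 1 fell and 15 did not pass (5 and 1 adjusted over the list alone), with a median of 0.90, camera adjusted p = 4.1e-04 and adjusted p = 0.447 with an estimated correlation. The list did not pass with clusters 7 and 8 added (median 0.10), and its median was 0.51 without Healthy 3, 0.52 without EAE 2, 1.58 without EAE 1 and 1.22 counted once. Rbp4, which carries retinol in blood, rose by 1.74 (SE 0.34) with overlap between the states, and Slc6a13, a GABA and taurine transporter, fell by 1.14 (SE 0.20). Rbp4 had a log2 fold change of -0.59 when clusters 7 and 8 were added to the class, and 2.55 without overlap counted once. Of 21 Wnt and BMP genes 3 rose, 3 fell and 15 did not pass (5 and 4 adjusted over the list alone), with a median of 1.11 and camera adjusted p = 0.0788, so the list did not pass. It did without Healthy 1 or Healthy 3 (adjusted p = 0.00868 and 0.0137, medians 1.45 and 0.64) and counted once (1.68, adjusted p = 0.0138), while clusters 7 and 8 gave an adjusted p of 0.983. The median was 1.51 without EAE 1 and 0.63 without EAE 2. Without Healthy 3, EAE 1 or EAE 2 the folds came from 1 batch alone. The median of the Wnt and BMP genes was 0.30 with thinning and 0.24 with marker scores, and it changed sign to -0.08 with clusters 7 and 8. The transcription regulator Id2 rose by 1.29 (SE 0.27), at under 20% of its level in another class, and Dkk2, which binds Wnt co-receptors, rose in CPM from 2.25, 4.42 and 2.26 to 12.7 and 17.8. The Wnt antagonist Frzb fell by 1.51 (SE 0.19) and Lef1 fell by 1.41 (SE 0.28). Of 22 growth factors and receptors 4 rose, 3 fell and 15 did not pass (5 and 4 adjusted over the list alone), with a median of 0.44 and camera adjusted p = 0.350. The median was 0.15 without Healthy 3, 0.20 without EAE 2 and 0.96 without EAE 1. Counted once that list passed (median 0.84, adjusted p = 0.0377, with 0.0377 to 0.983 over its alternatives). Fgf7 rose by 1.14 (SE 0.25) and Pdgfrb, a receptor of mesenchymal cells, by 1.02 (SE 0.23), while the neurotrophin receptor Ngfr fell by 2.73 (SE 0.29) and Fgfr1 fell by 1.01 (SE 0.21). Counted once Fgf7 had 1.77 and Pdgfrb 1.66, and Dkk2 had 0, 1 and 2 UMIs in Healthy. Apart from Frzb and Ngfr, the genes named here did not pass without Healthy 2 (1.72 for Rbp4, -1.13 for Slc6a13, 1.34 for Id2, -1.49 for Lef1, 1.11 for Fgf7, 1.03 for Pdgfrb and -1.06 for Fgfr1, with Dkk2 also not), nor did Pdgfrb without Healthy 3 (0.62).

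Genes of adventitial-type fibroblasts moved apart. Of 17 measured members 2 rose, 6 fell and 9 did not pass (2 and 6 adjusted over the list alone). Gsn and Cd34 fell as above, while Cd248, a membrane glycoprotein of stromal cells, rose by 1.10 (SE 0.20) and the fibrillin Fbn1 by 0.86 (SE 0.19). The camera test pointed down with adjusted p = 0.0185, and adjusted p = 0.447 with an estimated correlation. The list's mean was -0.18 but its median 0.15, so these differ in sign, and the median was 0.03 without Healthy 2, 0.09 without Healthy 3 and 0.06 without EAE 2. Without EAE 1 the list did not pass (adjusted p = 0.917, with 5.8e-06 to 0.917 over its alternatives). Counted once its median was -0.15 and it did not pass either (adjusted p = 0.172). Of 20 glycolysis and hypoxia genes 2 rose, 1 fell and 17 did not pass (4 and 1 adjusted over the list alone; median 0.11, camera adjusted p = 0.449), the movers being Eno1 (1.10, SE 0.20), Hif1a (1.02, SE 0.23) and Ankrd37 (-1.64, SE 0.29). Of 23 respiratory chain genes 0 rose, 1 fell and 22 did not pass (0 and 1 adjusted over the list alone; median -0.01, camera adjusted p = 0.734), the faller being Cox6c (-0.86, SE 0.19). Cd248, Fbn1, Eno1, Hif1a, Ankrd37 and Cox6c did not pass without Healthy 2 (1.17, 0.88, 1.05, 1.07, -1.70 and -0.92), Fbn1 and Cox6c not without Healthy 3 (0.57 and -0.56), and Eno1 not without EAE 1 (0.66). Counted once Cd248 had 2.08, Fbn1 1.645, Hif1a 1.78 and Eno1 0.73, the last with overlap between the states. Of 23 genes that dissociation can induce, 0 rose and 0 fell by the edgeR test (3 and 4 adjusted over the list alone), with a median of -0.25 and camera adjusted p = 0.426. That list passed downward without EAE 2 (median -0.47, adjusted p = 0.00213) and without Healthy 3 (-0.48, 0.00611), while its median was 0.16 without EAE 1, with 3.5e-05 to 0.824 over its alternatives. Ccl19, Tgtp2, H2-Q4, Hist1h2ap, Saa1, Serpina3g and Serpina3n belong to families of near-identical genes, so the split of their reads is uncertain.

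**Figure D4:**
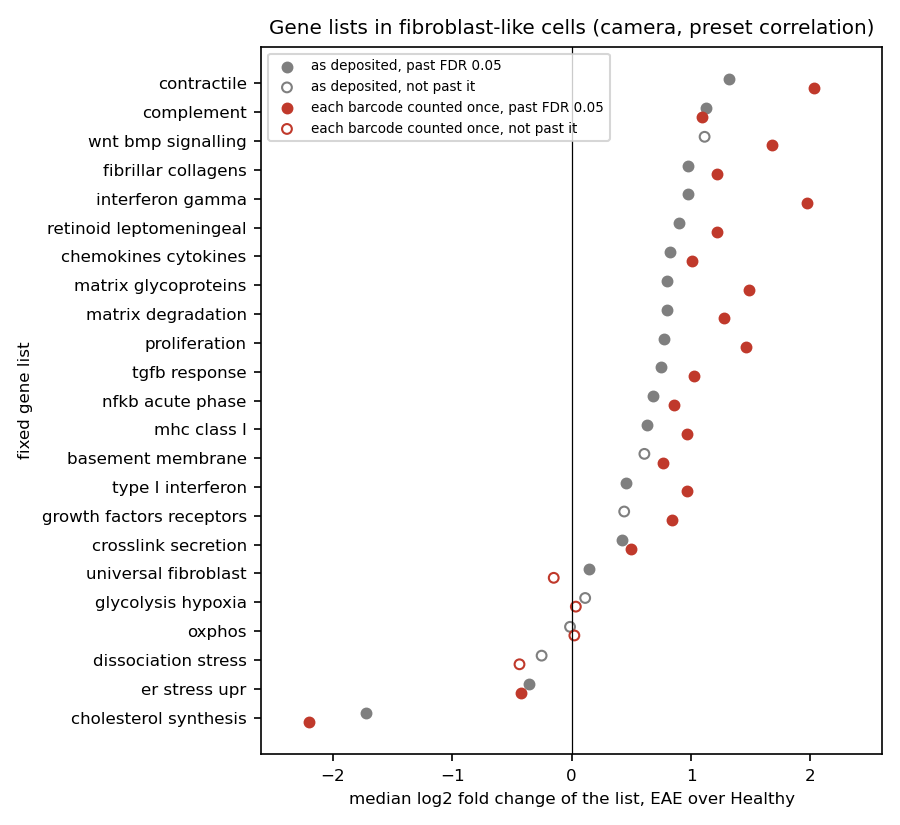
Median log2 fold change of EAE against Healthy in fibroblast-like cells for each tested gene list, as deposited (grey) and with each barcode counted once (red), filled where camera passed an adjusted p of 0.05 with a preset correlation. Cholesterol synthesis has the lowest median, -1.72 as deposited.

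Cluster 7 was compared by number. In other clusterings, clusters with its leading genes differed in weight between the states. Counted once before clustering, a cluster led by Clec3b and Fmod held 186, 44 and 59 Healthy and 6 and 6 EAE cells, and 1 led by Spp1 and Itih5 held 97, 30 and 70 and 101 and 68. With at least 1000 UMIs, a cluster led by Clec3b and Fmod held 159, 58 and 107 and 8 and 20 cells, and 1 with Spp1 and Saa1 among its leading genes held 7, 12 and 17 and 112 and 55. Saa1, an acute phase protein, rose by 4.58 (SE 0.40, edgeR adjusted p = 1.8e-04) on the log2 scale, from 34, 19 and 3 UMIs in the Healthy libraries to 469 and 184 in the EAE libraries. The cells of cluster 7 summed to 464215, 221823 and 485855 UMIs in the Healthy libraries and to 385042 and 309865 in the EAE libraries. Further risers near 0 UMIs in Healthy were the complement factor Cfb (2, 0 and 0 UMIs against 32 and 53), the haemoglobin-binding protein Hp (1, 0 and 0 against 10 and 37), the protease inhibitor Serpina3n (1, 1 and 1 against 27 and 41) and complement C6 (3, 1 and 1 against 38 and 38). Ptgds, which makes prostaglandin D, fell by 4.59 (SE 0.30, adjusted p = 2.1e-05), the chemokine Cxcl14 fell by 3.61 (SE 0.36) and the transporter Slc13a3 fell by 3.38 (SE 0.62). Angptl1 fell from 51, 38 and 67 UMIs to 1 and 1, and Flrt1 from 18, 10 and 10 to 0 and 1. Both EAE libraries lay on 1 side of all Healthy libraries for each of these 10 genes, which was a condition for naming them. Of 5693 genes tested 127 were higher and 84 lower, and 118 and 72 counted once. The counts were 171 and 145 without Healthy 1, 83 and 44 without EAE 1 and 127 and 135 without EAE 2. Counted once they were 212 and 189 without Healthy 1, 69 and 36 without Healthy 3 and 47 and 22 without EAE 1. DESeq2 gave 77 and 52. Flrt1 did not pass without EAE 1 (-2.52).

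**Figure D5:**
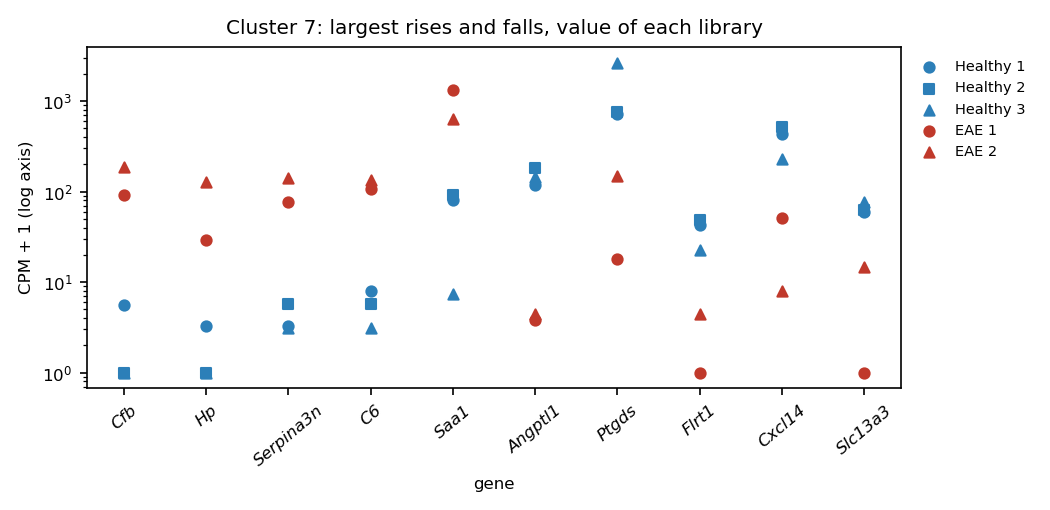
CPM plus 1 per library on a log axis in cluster 7 for the 10 genes named there, with Healthy libraries in blue and EAE libraries in red. Saa1 was at 1311 and 637 CPM in the EAE libraries and at 78.7, 90.9 and 6.44 CPM in the Healthy ones.

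In mural-like cells Ednrb, an endothelin receptor, rose by 3.52 (SE 0.43, edgeR adjusted p = 9.2e-04) on the log2 scale, from 5, 6 and 1 UMIs in Healthy to 118 and 59 in EAE, and Plac8 rose by 3.87 (SE 0.57), from 4, 6 and 0 to 90 and 125. Ednrb is among the 10 leading genes of cluster 15, whose weight in the class differed between libraries: cluster 11 held 55, 21 and 10 Healthy and 37 and 5 EAE cells, and cluster 15 held 36, 22 and 10 and 33 and 27. Counted once, Healthy 1 to 3 had 32, 21 and 10 cells in cluster 11 and 9, 15 and 10 in cluster 15. The class summed to 84978, 134715 and 91086 UMIs in the Healthy libraries and to 240657 and 184413 in the EAE libraries. Over library sizes scaled by TMM, Ednrb had 72.9, 53.7 and 13.4 CPM against 586 and 376. Serpina3g (4, 0 and 0 UMIs against 42 and 19), the carbonic anhydrase Car4 (2, 0 and 1 against 24 and 31) and Col15a1 (1, 2 and 1 against 21 and 61) rose as well. Txndc11, a thioredoxin-domain protein, fell by 2.58 (SE 0.49) and the bone morphogenetic protein Bmp2 fell by 2.51 (SE 0.57). The lipase Lipg fell from 15, 9 and 17 UMIs to 3 and 3. Cdh13 fell by 3.48 (SE 0.58) and Aldh1a1, from 2, 17 and 13 UMIs to 3 and 0, also fell as deposited, but neither passed counted once (adjusted p = 0.0645 and 0.0916). Both EAE libraries lay on 1 side of all Healthy libraries for each gene in CPM, which was a condition for naming them. Of 2591 genes tested in 91, 43, 20, 70 and 32 cells, 62 were higher and 35 lower, and counted once 45 and 17. The counts were 79 and 80 without Healthy 1 and 71 and 122 without EAE 1. Counted once, edgeR called 0 and 0 without EAE 1 (248 genes at an unadjusted p under 0.05), 16 and 0 without Healthy 3 (178), 17 and 6 without Healthy 1, 42 and 31 without Healthy 2 and 25 and 3 without EAE 2. Car4 did not pass without either EAE library, Serpina3g without EAE 1, Aldh1a1 without EAE 2, and Bmp2 in mural-like cells without EAE 2 (-1.35) or Healthy 3 (-1.34). With all barcodes DESeq2 called 25 and 29.

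Cluster 5 held most Healthy fibroblast-like cells counted once, so it was also tested alone. Ctgf, a matricellular growth factor, rose by 2.38 (SE 0.41), Inmt, a methyltransferase, by 2.31 (SE 0.31), and Wnt6, a Wnt ligand, by 2.63 (SE 0.48) on the log2 scale. Scgb1a1 (2.14, SE 0.31) and Man2a2 (2.27, SE 0.46) rose too. Dlk1 fell by 3.24 (SE 0.48), Col9a2 by 1.47 (SE 0.29), Htra1 by 1.22 (SE 0.25) and Gsn by 1.11 (SE 0.21). Both EAE libraries lay on 1 side of the Healthy libraries for each, which was a condition for naming them. Without Healthy 2 the calls of Wnt6, Ctgf, Man2a2, Col9a2, Htra1 and Gsn were lost (2.45, 2.22, 2.22, -1.47, -1.13 and -0.94). Those of Ctgf, Col9a2 and Htra1 were also lost without Healthy 3 (1.95, -0.91 and -1.05) or EAE 2 (1.88, -0.99 and -1.13), and those of Wnt6, Man2a2 and Gsn in cluster 5 without EAE 1 (3.22, 1.54 and -0.78). Of 6952 genes tested 21 were higher and 4 lower, and 18 and 4 counted once, from 54 and 61 EAE cells. With no batch term edgeR called 0 and 0 (545 at an unadjusted p under 0.05), while DESeq2 with the batch term called 15 and 3. The counts were 36 and 20 without Healthy 1, 13 and 2 without Healthy 2, 39 and 25 without EAE 1 and 27 and 12 without EAE 2. Counted once they were 23 and 12 without Healthy 1, 26 and 13 without Healthy 3, 20 and 11 without EAE 1 and 23 and 13 without EAE 2, and edgeR called 0 and 0 without Healthy 2 (327 at an unadjusted p under 0.05).

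Over all sorted cells, cell make-up included, 531 of 10663 genes were higher and 751 lower in EAE, and 911 and 973 counted once. With no batch term the counts were 15 and 114.

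The test of the difference in change between cell classes compared mural-like cells and cluster 7 with fibroblast-like cells within libraries. In cluster 7 the change of Saa1 was higher than in fibroblast-like cells by 4.15 on the log2 scale (SE 0.50, edgeR adjusted p = 0.00491, for the mix of cells given above). All 5 libraries followed its direction in cluster 7, as the rule that named it required. The fibroblast-like change of Saa1 itself was 0.43 (SE 0.20, adjusted p = 0.208). These values of Saa1 are as deposited. Saa1 is also among the 10 leading genes of the fibroblast-like cluster 9. That cluster held 161 and 60 cells of Healthy 1 and Healthy 2 as deposited, and 4 and 2 counted once. Whether copies lowered the fibroblast-like change of Saa1, and so raised the difference between classes, was not tested. In mural-like cells Col15a1 went up while it fell by 0.95 in fibroblast-like cells, and the difference passed (adjusted p = 2.6e-06, mural UMIs as above). Ednrb, among the leading genes of cluster 15, changed by 4.70 more in mural-like cells (SE 1.00, adjusted p = 0.00595, with the split over clusters 11 and 15 as above) and Txndc11 by -2.01 (SE 0.46, adjusted p = 0.0179). Over all genes 86 changes were higher and 88 lower in cluster 7 than in fibroblast-like cells, of 8574 tested, and 44 and 47 in mural-like cells, of 8289 tested.

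Fibroblast-like cells were clustered again without the 2365 called genes. Sub-cluster 3 held 47.0% ± 12.5 of EAE cells (SD, n = 2) and 2.44% ± 1.92 of Healthy cells (SD, n = 3), and sub-cluster 4 held 26.7% ± 12.9 and 1.24% ± 1.10. Sub-cluster 2 held 20.8% ± 1.9 of EAE cells and 38.5% ± 33.7 of Healthy cells as deposited, or 69.6% ± 14.005 of Healthy cells counted once. The exact two-sided permutation p was 0.2 for each of the 3 (counted once for sub-cluster 2, where it was 0.8 as deposited), the smallest that the test as run can give. The differences were 36.8 and 51.2 points in the first and second batch for sub-cluster 3, 34.0 and 17.5 for sub-cluster 4, and -43.9 and -57.3 for sub-cluster 2 counted once. As deposited the first-batch difference of sub-cluster 2 had the opposite sign, 2.80 points, with -57.3 in the second batch. As deposited sub-cluster 1 (a median of 620 UMIs per cell) held 44.9% ± 24.7 of Healthy and 4.32% ± 3.53 of EAE cells. Most of its Healthy cells were copies: Healthy 1 to 3 had 1171, 437 and 40 cells there as deposited and 155, 56 and 40 counted once. Counted once it held 26.1% ± 11.8 of Healthy cells, with differences of -28.0 and -11.8 points in the first and second batch.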

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

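The tests of shared barcodes against chance, of the likeness of shared barcodes, of separate EAE-like cells and of EAE-like cells in Healthy libraries, of recurring and of missing immune-like and pigment-gene cells, of the gap between batches over genes picked from the second batch, and of depth over genes tested in both were chosen only after the result was seen, as was counting each barcode once.

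The change of single genes between EAE and Healthy differed between cell classes in an edgeR test of the difference itself. In mural-like cells 44 changes were higher and 47 lower than in fibroblast-like cells (870 at an unadjusted p under 0.05), and 158 and 260 with barcodes counted once. In cluster 7 the numbers were 86 and 88 (1142), and 267 and 516 counted once. Among barcodes left out for having too few genes, 220 were in EAE 1 (10.2% of its 2156), with a median of 2455.5 UMIs, of which a median of 97.9% came from 4 haemoglobin genes. The other libraries had 9, 2 and 1 such barcodes in Healthy 1 to 3 and 1 in EAE 2, with medians of 0%, 0%, 98.3% and 96.4%.

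Healthy 1 and EAE 1 shared 185 times as many barcodes as chance gives, while libraries of different batches shared 15 where 12.4 were expected (1.21 times). Reuse of a barcode by different cells was argued against, because the profiles of a barcode in Healthy 1 and EAE 1 were more alike than those of different barcodes in 100% of 300 pairs. A median of 99.6% of the UMIs of a Healthy 1 copy lay in genes detected in the same barcode of EAE 1, against 72.7% for another EAE 1 cell of the same cluster, a median difference of 26.8 points over 1237 copies. A candidate explanation is that reads of 1 library were assigned to another of the same sequencing batch. Separate EAE-like cells of healthy cords were argued against as the source of shared barcodes, because 100% of the 1237 copies had more of their UMIs in genes of the EAE 1 cell with their barcode than of the other cell; that 36 of 1204 Healthy cells with a barcode in 1 library (2.99%) lay in clusters led by EAE (19 of 718, 6 of 116 and 11 of 370 in Healthy 1 to 3) says nothing on sharing, and transfer before sequencing was not tested.

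Of EAE 1 barcodes with over 5500 UMIs, 506 of 507 fibroblast-like ones recurred in Healthy 1 (99.8%), but 22 of 63 immune-like and pigment-gene ones did (34.9%), which left open whether these cells came from a further library. Only after that value was seen were they split, into 0 of 16 immune-like barcodes (0%, exact upper limit 20.6%, Fisher's exact p = 1.4e-29 against fibroblast-like ones) and 22 of 47 pigment-gene barcodes (46.8%). The immune-like cells of EAE 1 may thus have come from a further library, and for the pigment-gene cells the share lay between the bounds set, so both readings stay open. A different mix of male and female animals was argued against, with a difference in Y-linked share of 0 points, from 0 UMIs of 4 Y-linked genes against 5650 and 555 Xist UMIs. Removal of immune-like cells from the Healthy tables before deposit stays open (3 cells counted once, 4.04% of the 74.3 that the EAE share would give), as does entry of immune cells in EAE, which was not tested.

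The change in fibroblast-like cells was larger with barcodes counted once, and over 1221 genes picked from the second batch alone the gap between the median folds of the batches shrank by 68.9% (1.10 to 0.341), as copies of EAE 1 cells in Healthy 1 and Healthy 2 would give; over the genes that rose counted once it shrank by 93.3%, which decides nothing because they were picked from those calls. After thinning to 1000 UMIs 884 genes were called, against 2342 before (a count of 37.7%). That met the bound set beforehand for lower depth in Healthy cells, but 4154 rather than 8706 genes were then tested. Only after that value was seen was the test limited to genes tested in both, where 884 were called after thinning and 1397 before (63.3%). How many were called both times was not counted. Among the 1397, the fold after thinning was a median of 91.8% of that before, and 1395 kept their sign. As deposited, calls over genes tested in both went from 566 to 732. Thinning also dropped most first-batch Healthy cells as deposited (291 and 348 left of 1729 and 906), most of them copies, so depth stays open as a part of the cause. Genes called in the class had a median fold within cluster 7 of 34.5% of the class fold (same sign in 1218 of 1609) and within cluster 5 of 22.3% (1176 of 1671). These values cannot decide on a different mix of fibroblast clusters. Clusters were formed from expression, so folds would shrink within a cluster whether cells changed state or the mix changed. The mix stays open as well, and a difference between EAE and healthy cords that the design names remains among the explanations.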

How the results depend on the processing

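Counting each barcode once, alone or with other settings, leaving out both first-batch Healthy libraries, adding clusters 7 and 8, removing the 5% highest doublet scores, the share of cycling cells without thinning, and dropping the batch term in cluster 7, cluster 5 and mural-like cells were chosen after seeing the data. Of 2225 values of 75 fibroblast-like and 29 other named genes under the alternatives, 1920 were counted as kept, 303 kept direction but did not pass, and 2 changed sign. Kept meant the same direction and side of the threshold, except in fits of a single batch. Those gave 75 kept values for the first batch and 75 for the second, judged by direction alone without a threshold. For genes without overlap between the states that direction was already given. The count of higher genes in fibroblast-like cells was within 1.5 times of the reported one in 8 of 23 alternatives (1 to 1421) and that of lower genes in 11 of 23 (76 to 1209). Glycolysis and respiratory chain lists kept their side in 24 of 24 alternatives, and the immune-like share (without lymphocytes where these formed a class) and the mural-like share their sign in 13 of 13. Where no cause is named, the cause was not tested. No paired analysis was made, because the title of 1 EAE library carries no number (it is called EAE 1 here by its place in the order of samples), so that the titles share only the number 2. DESeq2 has no camera test, a minimum of 50 cells was not run for mural-like cells, and no library was left out in turn for all sorted cells or for the tests between classes. Depth limits the first-batch Healthy libraries most, where the median barcode had 615 and 913 UMIs.

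In fibroblast-like cells the counts of higher and lower genes were 1109 and 956 with no filter on low counts, where more genes are tested, 1 and 76 with no batch term, 1146 and 1169 with at least 1000 UMIs and at most 5% mitochondrial, 465 and 790 at resolution 0.5, 585 and 798 with clusters 7 and 8, 822 and 952 without the 5% highest doublet scores, 1202 and 1140 with barcodes counted once, and 1194 and 1148 when that was done before clustering. They were 394 and 293 without both first-batch Healthy libraries and with no batch term, where the lone Healthy library is assumed to vary like the EAE ones. Marker scores gave 355 higher, thinning to 1000 UMIs 379 higher, and equal cells per library 331 lower. Counted once, 758 were higher with DESeq2 and 1864 with no filter on low counts. Marker scores then gave 572 and 533, and thinning 477 and 407. In cluster 7 DESeq2 gave 77 and 52 and no batch term 66 and 40. In mural-like cells DESeq2 gave 25 higher, no batch term 21 and 10, and counting once 17 lower. With no batch term edgeR called 0 higher and 0 lower in cluster 5 (545 at an unadjusted p under 0.05, and 15 and 3 by DESeq2 with the batch term), and 15 and 114 over all sorted cells, where counting once gave 911 higher. The tests between classes gave 158 and 260 for mural-like cells and 267 and 516 for cluster 7 counted once.

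Leaving out 1 library gave 9 to 1421 higher and 132 to 1209 lower genes in fibroblast-like cells, and 523 to 1948 and 450 to 1547 counted once. The ranges, counted once included, were 47 to 212 and 22 to 189 in cluster 7, 0 to 79 and 0 to 122 in mural-like cells, and 0 to 39 and 0 to 25 in cluster 5. For lists the adjusted p ran from 0.00901 to 0.107 for fibrillar collagens, 0.00671 to 0.0615 for basement membrane, 5.6e-08 to 0.0594 for matrix glycoproteins, 7.9e-04 to 0.107 for crosslinking, 4.2e-09 to 0.0653 for NF-kappaB, 0.00229 to 0.0510 for Wnt and BMP, 0.0135 to 0.917 for adventitial-type genes, 0.00374 to 0.137 for the unfolded protein response, and 0.00213 to 0.621 for dissociation.

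Among lists that had passed, the camera adjusted p was over 0.05 for fibrillar collagens with no filter on low counts (0.0741), and for matrix glycoproteins with no batch term (0.101), resolution 0.5 (0.0506), marker scores (0.0975), clusters 7 and 8 (0.147) and equal cells (0.0685). For chemokines it was 0.212 with no batch term, 0.247 with marker scores, 0.110 with thinning, 0.0781 with clusters 7 and 8 and 0.0570 with equal cells. For NF-kappaB it was 0.0688 at resolution 0.5, 0.0570 with equal cells, 0.0624 with library totals and 0.0540 with no cell filter. For TGF-beta it was 0.368 with marker scores, 0.123 with thinning and 0.217 with clusters 7 and 8. With no batch term it was 0.239 for type I interferon, 0.0740 for class I presentation and 0.0621 for the unfolded protein response, which had 0.0796 with marker scores, 0.0797 with equal cells and 0.158 without both first-batch Healthy libraries. Matrix proteases had 0.198 and cell cycle genes 0.237 with marker scores, and retinoid genes 0.177 with clusters 7 and 8. Cell cycle genes pointed the other way after thinning (0.461). Adventitial-type genes had 0.437 with no filter on low counts, 0.0706 with at least 1000 UMIs, 0.231 with thinning, 0.172 counted once, 0.136 counted once before clustering and 0.824 without both first-batch Healthy libraries.

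Among lists that had not passed, basement membrane did with no batch term (0.0114), at least 1000 UMIs (0.0215), thinning (0.0404), counting once (0.00742) and counting once before clustering (0.00817). Wnt and BMP genes did with at least 1000 UMIs (0.00199), thinning (0.0210), without the highest doublet scores (0.00820), equal cells (0.0324), counted once (0.0138), counted once before clustering (0.0103) and without both first-batch Healthy libraries (0.00176). Growth factors did with thinning (0.0498), counted once (0.0377) and without both first-batch Healthy libraries (0.0493), and dissociation genes, downward, with marker scores (0.0158) and clusters 7 and 8 (3.5e-05). With an estimated correlation, every list that had passed was at 0.447 except contractile (0.480), TGF-beta (0.520) and NF-kappaB (0.532). That estimate rests on 5 libraries, so these values cannot tell changed lists from unchanged ones. With fry the adjusted p was 0.1505 for fibrillar collagens, matrix glycoproteins and retinoid genes, 0.114 for crosslinking, interferon-gamma, complement, cell cycle, adventitial-type and cholesterol genes, 0.159 for matrix proteases, 0.192 for contractile genes and chemokines, 0.229 for TGF-beta, 0.128 for type I interferon, 0.0816 for class I presentation and 0.259 for NF-kappaB.

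The fibroblast-like share differed by -7.54 points in the first batch and from -1.21 to 12.2 with 1 library left out, where the reported difference was 5.90. The share of cycling cells, reported as -1.04 points, was 1.12 in the second batch, 2.06 after thinning to 2000 UMIs, 0.540 with at least 1 UMI, 4.53 not thinned and 1.25 counted once. Rbp4 had a log2 fold change of -0.48 with marker scores and -0.59 with clusters 7 and 8.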

Other observations

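The genes and clusters described here were chosen after their values were seen, and counting each barcode once was also chosen after seeing the data.

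Cluster 14 (149 cells) was led by Dct, Pmel, Mlana and Tyrp1, genes of melanin-forming cells. It held 1.72%, 3.16% and 0.538% of Healthy 1 to 3 and 3.29% and 0.821% of EAE 1 and EAE 2, a difference smaller than the spread between libraries (exact permutation p = 0.8), and counted once 0.415%, 2.11% and 0.538% of the Healthy libraries. Mural-like cells formed 2 clusters of 128 cells each. Cluster 11 was led by Myh11, Pln, Cnn1 and Acta2, genes of contractile smooth muscle, and cluster 15 by Rgs5, Higd1b, Kcnj8 and Ednrb, genes of pericytes. Counted once, Healthy 1 to 3 had 32, 21 and 10 cells in cluster 11 and 9, 15 and 10 in cluster 15, and as deposited EAE 1 and EAE 2 had 37 and 5 in cluster 11 and 33 and 27 in cluster 15. Cluster 8, led by the cartilage matrix gene Comp and the transporter Slc47a1, was 5.40% of Healthy 2 counted once, and 0.415% and 0.269% of Healthy 1 and Healthy 3. The osteoblast genes in the fibroblast-like cells of Healthy 2, summing to 5709 CPM counted once over 8 markers, came mostly from Bglap and Bglap2, which encode osteocalcin.

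The genes in this paragraph, picked after their values were seen, passed with barcodes counted once and not as deposited, and in each both EAE libraries then lay above all 3 Healthy libraries. Timp1, an inhibitor of matrix proteases, had a log2 fold change of 2.78 as deposited (edgeR adjusted p = 0.480) and 6.13 (SE 0.38) counted once, with 1940 and 678 CPM in EAE against 52.4, 18.8 and 5.53. Fn1, fibronectin, went from 1.51 (adjusted p = 0.293) to 2.73 (SE 0.20), and complement C4b from 2.09 (adjusted p = 0.200) to 3.78 (SE 0.28). The contractile genes Acta2 and Tagln had 1.97 and 2.15 (adjusted p = 0.330 and 0.290) as deposited and 3.28 (SE 0.47) and 3.74 (SE 0.31) counted once. Both are also mural markers. Counted once, those markers summed to 917 and 1179 CPM in the fibroblast-like cells of EAE and to 649, 577 and 463 CPM in those of Healthy. The limit for RNA of other classes was not applied to the genes of this paragraph, so RNA of mural-like cells stays open for these. As deposited, the second batch alone gave 6.80 for Timp1 and 2.94 for Fn1, and the first batch 0.85 and 0.52.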
